A study of Mus musculus with 40 samples.

How the data were processed

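RNA from random lung sections of female C57BL/6 mice was measured on 40 2-colour Agilent whole-mouse-genome arrays, 1 animal per array. Lung RNA carried Cy5 and a universal mouse reference RNA carried Cy3 on every array, with no dye swap. The 8 groups were 2 times (day 1 and day 28 after a single intratracheal instillation) by 4 doses of anatase titanium dioxide particles (0, 54, 162 and 486 µg per animal), with 5 animals each. The labels call them nanoparticles and give a diameter of 300 nm. The arrays sat on 10 slides of 4, and each slide held 1 animal of every dose at 1 time. Replicate numbers here are names given in the order of the samples. They run along the slides, so that replicates 1 to 5 of day 1 are slides 1, 3, 5, 7 and 9 and those of day 28 are slides 2, 4, 6, 8 and 10. A dose of 18 µg and a day 90 that the series text mentions were not analysed here. What the 0 µg animals were given, and the time of day at collection, are not stated in the labels.

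Per the file headers, the arrays were read with Agilent Feature Extraction 11.0.1.1 under the protocol GE2_1100_Jul11. The files hold the median signal and median background of each spot as scanner intensity, per the file headers, and mean signals were not used here. A further column holds the ratio of Cy5 to Cy3 on a log10 scale, per the file headers, after the software's own background correction and dye normalisation. A table with 1 value per probe and array was deposited without a stated unit. Read as log2 ratios of lung over reference, the deposited values were compared across probes with loess ratios made here. Without background subtraction r was between 0.994 and 0.998. With it, as in the main results, r was between 0.939 and 0.995, and lowest for replicate 4 of 162 µg at day 28. The medians of the deposited values per array lay between -0.0452 and -0.0132. The authors' scaling and centring of that table stay unknown beyond this, and it served as an alternative only.

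Each array held 43379 spots apart from 1639 control spots, which had weight 0. Spots that the software marked as non-uniform or as population outliers were set to missing, between 87 and 404 per array. Background was removed from the median signals by the normexp model with an offset of 50, and log2(Cy5/Cy3) was normalised within each array by loess in limma 3.58.1 (R 4.3.3, the data.table package, version 1.17.8). Of 41174 probes, 27479 were matched through their RefSeq accession to 1 gene symbol in a table of the GRCm38.p6 assembly, 13695 were not matched and entered under their own names, and 0 matched several symbols. The array files name mm9 as their build, so the table served for names only and no coordinates are given. A gene measured by several probes was represented by the probe with the highest mean log2 Cy5 signal, among probes with Cy5 well above background on at least 5 of the 40 arrays. Genes also needed a value on at least 3 arrays of each group, which left 23876 genes for testing. Genes whose probes stayed near background were not tested, so a change between undetectable levels and levels just above background can be missed. Levels are log2 ratios to the reference RNA, so they compare groups for 1 gene and do not rank genes by abundance.

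Cy5 was well above background for 58.6% to 74.0% of probes per array and Cy3 for 50.0% to 67.9%. The median Cy5 signal of an array was between 107 and 176, over a median background between 69.5 and 90. Across all arrays 0 Cy5 spots were saturated. The number of arrays limits the precision of every value.

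Groups were compared with limma's moderated linear model, with 8 groups and the slide as a fixed block over all 40 arrays (24 residual degrees of freedom). p was adjusted by the Benjamini-Hochberg method over all genes of a comparison, and a gene was called at an adjusted p below 0.05. There were 14 comparisons: each dose against 0 µg at each time, the difference between times in each of these responses (the interaction), the linear trend over the 4 dose steps at each time, 486 against 162 µg at each time, and day 28 against day 1 at 0 µg. Since every slide held 1 time only, the last comparison used the slide as a random block, with an estimated correlation of 0.369 between arrays of a slide. Folds are 2 to the power of the log2 difference. SE is the standard error of the moderated model, SD the spread of the 5 arrays of a group, and the number of slides with the called sign is given as a count out of 5.

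A total of 34 gene lists were written from general knowledge of lung responses to particles, of lung cell types and of neighbouring tissues. Each was tested with limma's camera at a preset correlation of 0.01 between genes in the 6 comparisons with 0 µg and the 3 interactions, and p was adjusted over the 306 tests. Camera with an estimated correlation was run beside it. Members called over all genes are counted beside members called with p adjusted over the list alone. Lists share members: Timp1, for one, belongs to the acute phase and the matrix list, and Ccl17 to the CC chemokine, type 2 and dendritic cell lists. The gene now named Bmal1 is Arntl in the gene table.

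Genes to be named were chosen by a rule: among called genes with 1 sign on all 5 slides, a name in the gene table and Cy5 well above background on at least 4 of 5 arrays of the higher group, the 10 largest rises and 10 largest falls at 486 µg and 4 of each at the lower doses. Where no gene was called, the 3 with the smallest p were taken. The 3 members with the smallest p of each list past the threshold were added, and so were 10 fixed markers (Saa3, Cxcl5, Ccl2, Ccl7, Il6, Spp1, Timp1, Mmp12, Arg1 and Col1a1). Carried out in full, the rule gave 327 values. So many lists passed that values are described in detail for 80 genes, a narrowing made after the lists had been tested. Groups, tests, lists, this rule and the alternatives were fixed before the data were examined, with the exceptions that are named where they occur.

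The alternatives were no background subtraction, the software's log10 ratios, the deposited value table, Cy5 alone with quantile normalisation, loess followed by scaling between arrays, no filter or a stricter filter (20 of 40 arrays) on dim probes, the mean over all probes of a gene, no slide block, the slide as a random block, the 20 arrays of 1 time alone, array weights, a 1.5-fold minimum, each array left out in turn, 0 µg arrays split between doses, and an estimated correlation for lists. Chosen after seeing the data were each slide left out in turn, slides 2 and 10 left out together, and 3 arrays of 162 µg left out together. The labels of the arrays were also regrouped 100 times per comparison, and separately within slides where a slide held the groups compared. The model fit and the calling were tested on simulated log2 ratios, in which 200 of the 23876 genes were changed per comparison with 0 µg. Noise was drawn independently for each gene and array. Background correction, loess, the choice of probes and arrays that stand apart were not part of this test, so its rates need not hold for these data. For the 6 comparisons with 0 µg it recovered 62.7% to 80.6% of genes changed by a log2 of 0.5 and 92.5% to 97.0% of those changed by a log2 of 1, and it called 5 to 11 unchanged genes. Figures were drawn with matplotlib 3.10.9 and numpy 2.4.6 in Python 3.11.15.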

Results

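Messenger RNA was measured in the lungs of 40 mice, 5 for each combination of 2 times and 4 doses of anatase titanium dioxide nanoparticles. The particles, of 300 nm diameter by the labels, were instilled into the trachea once, and lungs were taken 24 h or 28 days later. The series title speaks of fibrosis-like changes at high doses. The comparisons therefore ask which genes changed 1 day after each dose, which were changed at day 28, and whether the response differed between the times. Arrays of a group correlated with each other at r between 0.853 and 0.975 across genes, which are not independent replicates. The lowest correlations with the median of the 40 arrays were 0.92 for replicate 4 of 162 µg at day 28, 0.931 for replicate 3 of 162 µg at day 1 and 0.939 for replicate 5 of 0 µg at day 28.

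**Figure D1:**
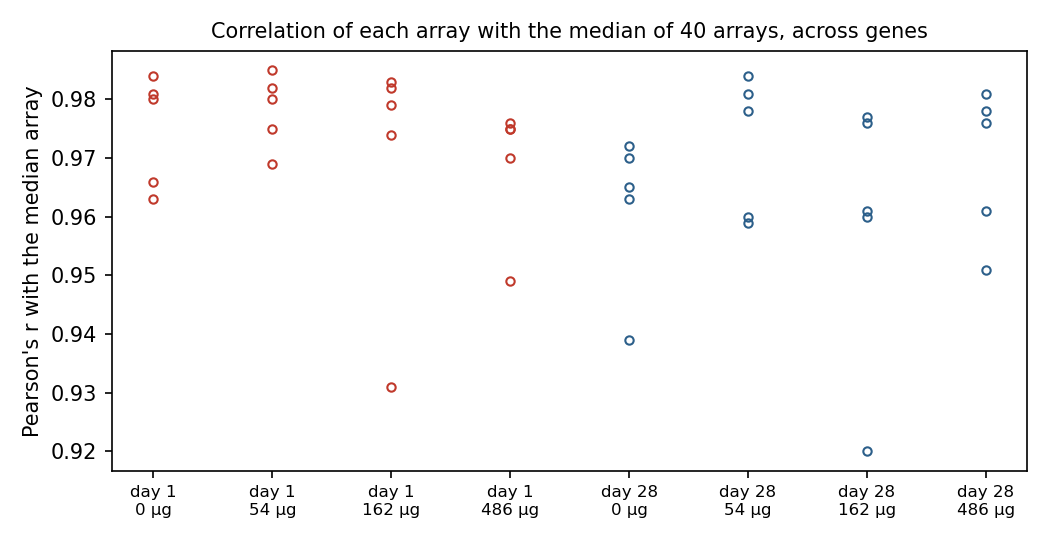
Pearson correlation across genes of each array with the median of the 40 arrays (y axis, no unit), by group of day and dose (x axis), with 1 point per array. The lowest points are 0.92 in the 162 µg group of day 28 and 0.931 in the 162 µg group of day 1.

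At day 1, lungs given 486 µg held more mRNA for acute phase proteins and for chemokines that draw leukocytes than lungs given 0 µg. Saa3, a serum amyloid A made in lung and other tissues during the acute phase, was 73.5-fold higher (log2 6.20, SE 0.692, n = 5 per group, adjusted p 4.17e-06). Its level was 3.16 ± 1.03 against -3.05 ± 0.398 (mean log2 ratio to the reference ± SD), and it was higher on 5 of 5 slides, by 4.66 to 7.18. Timp1, an inhibitor of matrix metalloproteinases, was 6.96-fold higher (log2 2.80, SE 0.29, n = 5, adjusted p 1.27e-06). Lcn2, an iron-scavenging protein of neutrophils and inflamed epithelium, was 8.36-fold higher (log2 3.06, SE 0.403, n = 5, adjusted p 4.92e-05). Ccl2, which attracts monocytes, stood at -2.72 ± 0.45 against -4.27 ± 0.31, a 2.93-fold difference (SE 0.257 on the log2 scale, n = 5, adjusted p 0.00139). All of these genes were higher on 5 of 5 slides.

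Of 26 measured acute phase genes, 12 rose and 0 fell at this dose and time (16 rose with p adjusted over the list alone), with a median log2 difference of 0.69. Beside Saa3, Lcn2 and Timp1 they included Saa1 (log2 3.04, SE 0.303), Saa2 (2.16, SE 0.175) and Orm2 (1.95, SE 0.194). The probes of Saa1 and Saa2, and of Orm1 and Orm2, may not separate such similar sequences, so the member of each pair is uncertain. The list passed camera with the preset correlation (adjusted p 8.87e-38) and with an estimated correlation (0.000173). Of 18 neutrophil chemoattractants and related cytokine genes, 9 rose and 0 fell (10 and 0 over the list alone; adjusted p 5.32e-20, and 3.89e-05 with an estimated correlation). Il1rn, the IL-1 receptor antagonist, rose by 0.75 (SE 0.085), and Tnfaip3 and Nfkbia, inhibitors that NF-kappaB itself induces, rose by 0.45 (SE 0.0647) and 0.48 (SE 0.0744). Of 18 CC chemokines, 6 rose and 0 fell (10 and 1 over the list alone; adjusted p 3.68e-15, and 0.0022 with an estimated correlation). Ccl7 rose by 1.59 (SE 0.188), Ccl17, a chemokine for T cells, by 1.38 (SE 0.222) and Ccl12 by 0.79 (SE 0.0949), although Ccl12 and Ccl2 are alike in sequence. These 3 lists were the only ones of the 34 at any dose against 0 µg whose call held with an estimated correlation.

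**Figure D2:**
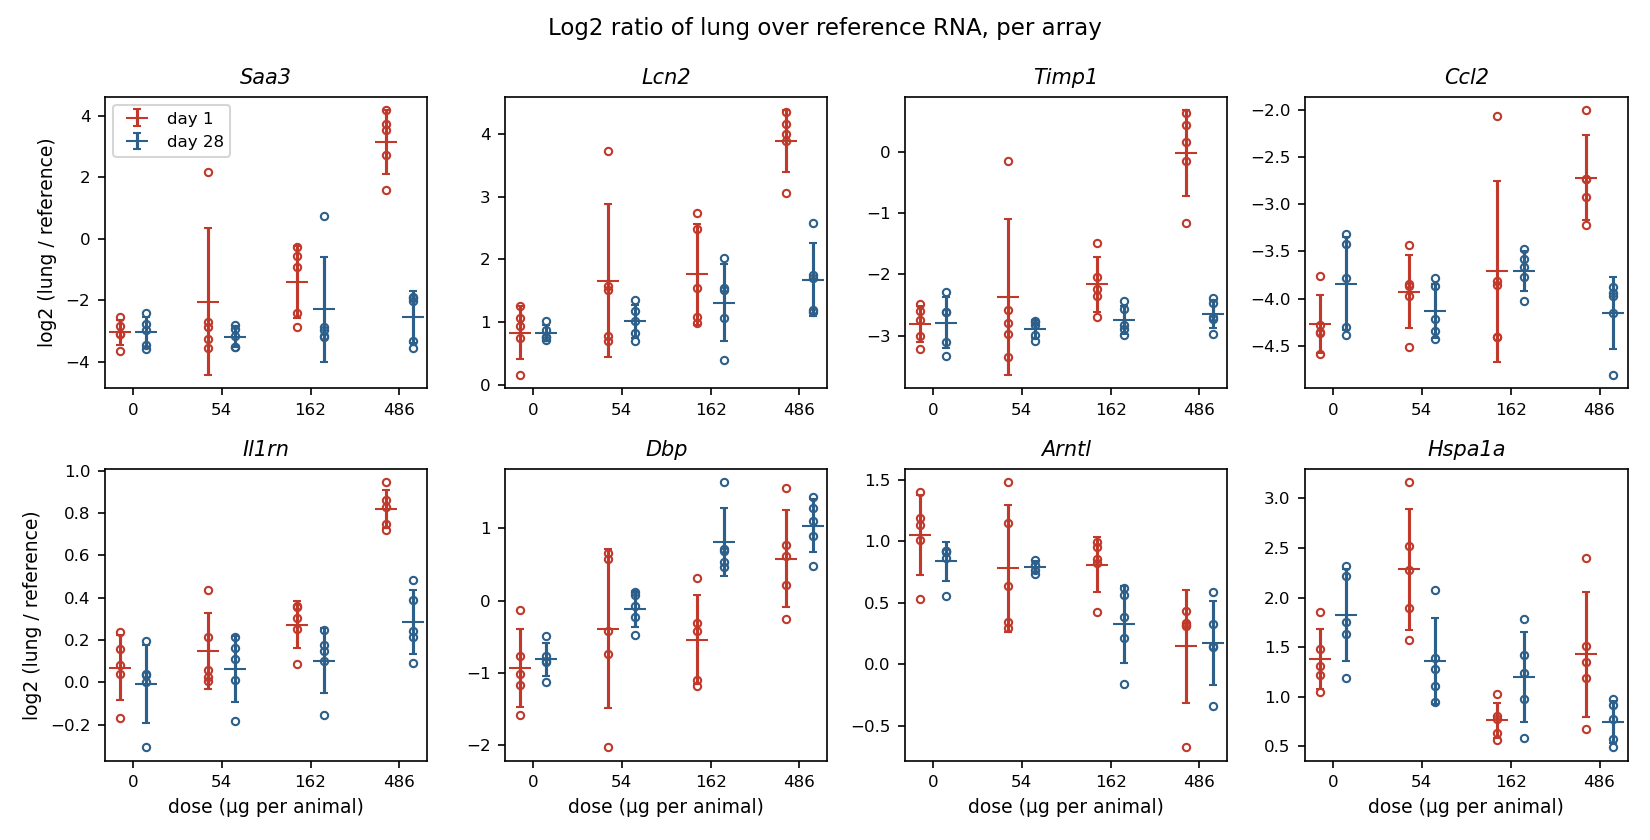
Log2 ratio of lung to reference RNA (y axis) against dose in µg per animal (x axis) for Saa3, Lcn2, Timp1, Ccl2, Il1rn, Dbp, Arntl and Hspa1a. Open circles are arrays, dashes are means of 5 and bars are SD, in red for day 1 and blue for day 28; Saa3 averages 3.16 at 486 µg on day 1 against -3.05 at 0 µg.

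Of 22 neutrophil marker genes, 5 rose and 0 fell (11 and 0 over the list alone, median 0.43, preset adjusted p 3.27e-13). That list's call was lost with an adjusted p = 0.0845 with an estimated correlation. Il1r2, the decoy receptor for IL-1, rose by 1.00 (SE 0.105). Csf3r, the G-CSF receptor, rose by 0.72 (SE 0.155), while for Cxcr2 (0.72, SE 0.157) another probe gave -0.026. Among 18 complement genes, C3 (log2 1.49, SE 0.231) and Cfb (1.09, SE 0.19) rose and 0 fell (3 and 0 over the list alone; median 0.16; adjusted p = 0.524 with an estimated correlation). Of 21 genes of type 2 immunity, 1 rose (6 over the list alone; median 0.30; adjusted p = 0.331 with an estimated correlation). Of 28 lysosome genes, Ctsb and Plin2 rose (5 over the list alone; median 0.14; adjusted p = 0.331 with an estimated correlation), and another probe of Ctsb had the other sign. Of 28 interferon response genes, 2 rose, Cxcl10 (0.99, SE 0.183) and Ifit1 (3 over the list alone; median 0.13; adjusted p = 0.525 with an estimated correlation). Of 32 cell cycle genes, Mcm2 and Mcm6 of the replicative helicase rose (5 over the list alone; median 0.03; adjusted p = 0.805 with an estimated correlation).

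The series title makes genes of the extracellular matrix of interest. Of the 32 measured in the list for it, 2 rose after 486 µg at day 1, Timp1 and Tgfbi, with the same 2 over the list alone (median 0.08; preset adjusted p 0.0135; adjusted p = 0.525 with an estimated correlation). Col1a1, a chain of type I collagen, differed by 0.07 (SE 0.144, adjusted p 0.982) and Spp1 by 0.39 (adjusted p 0.85). Arg1, an enzyme of alternatively activated macrophages, differed by 0.30 (adjusted p 0.593). Matrix genes outside the list were called in both directions, among them Mmp3 (0.77), Efemp2 (0.48), Adamts5 (-0.55) and Htra1 (-0.42), and were not tested as a group. Il6 was well above background on 2 arrays of this group, and Mmp12 on 1, and neither was tested.

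Fewer genes fell after 486 µg at day 1. Adm, which encodes the vasodilator adrenomedullin, was 2.09-fold lower (log2 -1.06, SE 0.189, n = 5, adjusted p 0.00307). Ogn, a small proteoglycan of the matrix, was lower by a log2 of -0.68 (SE 0.109) and Gstm1, a glutathione S-transferase, by -0.69 (SE 0.131); probes for Gstm and Gsta genes may not separate family members. All 3 were lower on 5 of 5 slides. Of 18 xenobiotic metabolism genes, 0 were called over all genes and 2 fell over the list alone (median -0.14; adjusted p = 0.366 with an estimated correlation). Of 28 oxidative stress genes, 1 rose and 3 fell (3 and 5 over the list alone). Their median was -0.0035 and their mean 0.0095, and the list did not pass (adjusted p 0.575).

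Of 18 clock genes, 4 rose and 1 fell (6 and 2 over the list alone; median 0.07; adjusted p = 0.334 with an estimated correlation). Dbp, a transcription factor that clock proteins drive, was 2.85-fold higher (0.58 ± 0.67 against -0.93 ± 0.538; SE 0.31 on the log2 scale, n = 5, adjusted p 0.0122). Arntl, the core activator of the clock, was 1.87-fold lower (log2 -0.91, SE 0.192, n = 5, adjusted p 0.0166), and Bhlhe40, a clock repressor, was higher by 0.58 (SE 0.095). Without replicate 1 or 5 of 486 µg or replicate 4 of 0 µg, Dbp was no longer called (adjusted p up to 0.081). The same arrays and replicates 1 and 5 of 0 µg each ended the call of Arntl (up to 0.0853).

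For the remaining lists at day 1 after 486 µg, calls over all genes and over the list alone were few. The heat shock list (22 genes, 0 called and 4 up over the list alone, median 0.13) had an adjusted p = 0.366 with an estimated correlation. Cholesterol synthesis (23 genes, 0 and 1 up, median 0.14) had 0.331, alveolar macrophages (19 genes, 0 and 4 up, median 0.12) 0.606, and monocytes with interstitial macrophages (23 genes, 0 and 0, median 0.09) 0.696, each as adjusted p with an estimated correlation. Ciliated cells (27 genes, 0 and 0, median -0.19) had an adjusted p = 0.709 and cardiomyocytes (24 genes, 0 and 0, median -0.38) an adjusted p = 0.778 with an estimated correlation. All 6 passed at the preset correlation. Lists that did not pass even there were dendritic cells (2 of 16 up over all genes and over the list alone, adjusted p 0.066), fibroblasts and pericytes (1 of 25 up by either count, 0.0713) and glucocorticoid targets (0 of 14, 0.0803). The others were club and goblet cells (0.184), alveolar type 1 cells (0.329), adipocytes (0.329), endothelium (0.435), T and NK cells (0.46), B cells (0.524), eosinophils with basophils and mast cells (0.576), erythroid cells and platelets (0.707), mesothelium (0.879), smooth muscle (0.904), alveolar type 2 cells (0.952) and thymus with lymph node (0.97).

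limma called 187 of 23876 genes at day 1 after 486 µg, 141 higher and 46 lower, and 1755 had an unadjusted p below 0.05 where chance alone expects 1194. Of the 187, 74 differed by at least 1.5-fold and 32 by at least 2-fold. The count was 100, 83 and 84 without replicates 1, 3 and 4 of 0 µg, and 98, 117 and 91 without those of 486 µg. Of 40 genes named by the rule and called here, 23 stayed called with each of the 10 arrays left out in turn. Cxcl5, a neutrophil chemoattractant (log2 1.81, SE 0.434, adjusted p 0.0396), stayed called only without replicate 1 of 486 µg, and its adjusted p reached 0.197. Gsta1 (-0.75) was lost without replicate 4 of either group (up to 0.0613), and Asgr1 (-0.91) and Ctsb (0.40) also without replicate 3 of 0 µg (up to 0.0887 and 0.0832). Tgfbi (0.80), Mcm2 (0.58) and Mcm6 (0.51) were lost without replicate 1, 3 or 4 of either group, Mcm6 also without replicate 5 of 486 µg (up to 0.148, 0.182 and 0.296). Csf3r was lost without replicates 3 or 4 of either group, Cxcr2 without replicate 4 of either, 2 of 486 µg or 3 of 0 µg, and Plin2 (0.38) without replicates 1 or 4 of either (up to 0.125, 0.129 and 0.0765). Gsta3 (-0.61), Pcolce2 (-0.56), Ifit1 (0.37), Rasl11a (-0.64) and Bcan (-0.79) were lost in 5, 6, 7, 8 and 9 of the 10 leave-outs (adjusted p up to 0.135, 0.222, 0.184, 0.19 and 0.239).

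At the lower doses of day 1, none of the fixed markers that were tested passed, and several differences rested on 1 animal. Saa3 differed by a log2 of 1.00 at 54 µg and 1.64 at 162 µg (SE 0.692 for each, n = 5 per group), with adjusted p of 1 and 0.974. At 162 µg it was higher on 5 of 5 slides. Timp1 differed by 0.44 and 0.65, Ccl2 by 0.35 and 0.56, Cxcl5 by 0.45 and 0.42, Ccl7 by 0.28 and 0.21 and Spp1 by 0.27 and 0.61. Col1a1 differed by -0.13 and 0.21, and Arg1 by 0.20 and -0.04. At 54 µg replicate 3 stood 5.28 above the mean of the other 4 arrays for Saa3 and 2.78 for Timp1, and without it the differences were 0.11 (SE 0.612) and -0.02 (SE 0.214). At 162 µg replicate 3 stood 2.42 above the others for Spp1 and 2.05 for Ccl2, and without it the differences were 0.19 (SE 0.198) and 0.19 (SE 0.209).

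limma called 0 genes at 54 µg and 0 at 162 µg on day 1, with 867 and 1171 genes at an unadjusted p below 0.05. The smallest p at 54 µg belonged to 1700120E14Rik, which was well above background on 1 of 5 arrays there and 0 of 5 at 0 µg, to Accs (-0.36, SE 0.0696, adjusted p 0.224) and to H2-T22, a class I histocompatibility gene (-0.35, SE 0.0714, adjusted p 0.336). At 162 µg they belonged to Olfr1216, near background on most arrays, to Enc1 (0.26, SE 0.0598) and to Dynll1 (-0.26, SE 0.0587), whose other probe had the other sign; each had an adjusted p of 0.964. At 54 µg, 21 of 22 heat shock genes lay above the 0 µg level, with 0 called over all genes and 5 over the list alone (median 0.22, preset adjusted p 2.42e-12; adjusted p = 0.077 with an estimated correlation). Of 28 interferon genes, 0 were called and 4 fell over the list alone (median -0.10; adjusted p = 0.24 with an estimated correlation). Cardiomyocyte genes had a median of 0.69 at that dose (adjusted p = 0.525 with an estimated correlation). At 162 µg, cell cycle genes had a median of 0.31 (0 called by either count; adjusted p = 0.366 with an estimated correlation) and club and goblet cell genes one of -0.49 (adjusted p = 0.606 with an estimated correlation). Replicate 3 of that group stood apart from the other arrays of its slide in the same lists, by 0.665 for cell cycle and -1.44 for club and goblet cells, and replicate 5 by 0.534 for cell cycle. In all, 17 lists at 54 µg and 11 at 162 µg passed at the preset correlation, and 0 held with an estimated one.

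**Figure D3:**
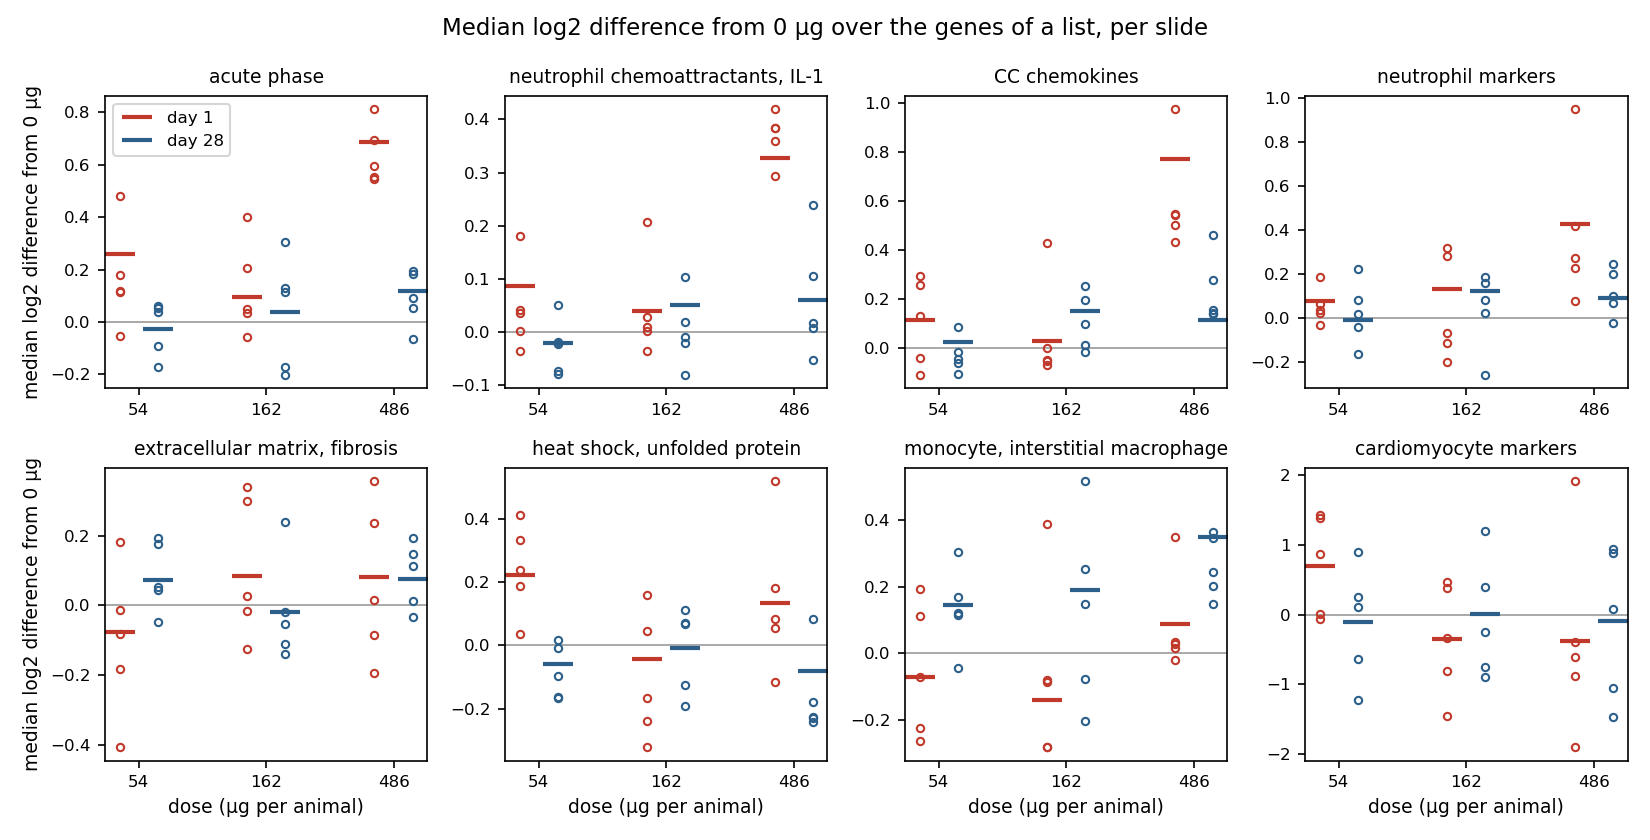
Median log2 difference from 0 µg over the genes of a list (y axis) against dose in µg per animal (x axis) for 8 lists, red for day 1 and blue for day 28. Circles are the 5 slides and dashes the median over all arrays; the acute phase median is 0.69 at 486 µg on day 1 and 0.12 on day 28.

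At day 28, the largest called differences between lungs given 486 µg and 0 µg were a rise of Dbp and a fall of Hspa1a. Dbp was 3.6-fold higher (1.03 ± 0.369 against -0.81 ± 0.226; SE 0.31 on the log2 scale, n = 5, adjusted p 0.0046), and Hlf, a related factor under clock control, was higher by 0.69 (SE 0.135, adjusted p 0.0144). Hspa1a, an inducible HSP70 of the heat shock response, was 2.11-fold lower (0.75 ± 0.21 against 1.82 ± 0.459; SE 0.235, adjusted p 0.0268), and its co-chaperones Dnaja1 and Dnajb1 differed by -0.82 (SE 0.141) and -0.74 (SE 0.118). Pde4b, a phosphodiesterase that breaks down cAMP, was 1.82-fold lower (log2 -0.86, SE 0.137, adjusted p 0.00322), and Klf4, a transcription factor of epithelium and monocytes, differed by -0.85 (SE 0.152, adjusted p 0.00637). Ahr, the aryl hydrocarbon receptor, was 1.55-fold higher (log2 0.63, SE 0.105, adjusted p 0.0046). All of these had 1 direction on 5 of 5 slides.

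Of the acute phase, CC chemokine and matrix lists, 1 gene, Ccl12, was called at that time. Saa3 differed by 0.49 (SE 0.692, adjusted p 0.804), Timp1 by 0.14 (adjusted p 0.874), Ccl2 by -0.31 (adjusted p 0.635), Ccl7 by -0.17, Cxcl5 by 0.12, Spp1 by -0.11 and Arg1 by 0.12. Col1a1 differed by 0.20 (SE 0.144, adjusted p 0.582), and 0 of 32 matrix genes were called by either count (median 0.08, preset adjusted p 0.162). Acute phase genes had 0 of 26 called by either count, a median of 0.12 and an adjusted p = 0.612 with an estimated correlation. Of 18 CC chemokines 1 rose, Ccl12 (0.45), by either count (preset adjusted p 0.0968).

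Most macrophage markers, and alveolar type 2 cell markers as a list, lay above the 0 µg level at day 28 after 486 µg, by amounts that differed between slides. All 19 alveolar macrophage markers were above it, with 0 called over all genes and 2 over the list alone (median 0.34, preset adjusted p 2.14e-06). Its adjusted p = 0.366 with an estimated correlation. The median was 0.702 on slide 2 and between 0.131 and 0.395 on the other 4 slides. On slide 2 the 0 µg array, replicate 1, stood low: its alveolar macrophage markers lay at -0.74 from their mean over the 40 arrays, T and NK cell markers at -0.642, endothelial markers at -0.421 and alveolar type 2 markers at -0.334. Club and goblet cell markers lay at -0.687 and ciliated cell markers at -0.574. The slope of this array's log2 ratios on those of the median array was 0.802, against 1.02 for the 486 µg array of slide 2. Such a difference of scale between arrays was not separated from a change in cells. Of 23 markers of monocytes and interstitial macrophages, 0 were called over all genes and 8 rose over the list alone (median 0.35; adjusted p = 0.372 with an estimated correlation), with medians per slide between 0.149 and 0.364. Dendritic cell markers (0 and 4 up, median 0.18; adjusted p = 0.331 with an estimated correlation), type 2 immunity (0 and 6 up, median 0.32; 0.366) and complement (0 and 1 up, median 0.35; 0.489) lay above it likewise. B cell markers had 1 of 20 up, Fcrla (0.63, SE 0.138), and 4 over the list alone (adjusted p = 0.525 with an estimated correlation); Cd22 differed by 0.59 (adjusted p 0.14) with another probe of the other sign. In the heat shock list 4 of 22 fell (1 up and 6 down over the list alone; median -0.08; adjusted p = 0.426 with an estimated correlation), all 4 of them cytosolic chaperones. Of 18 clock genes 2 rose, Dbp and Hlf (5 up and 2 down over the list alone; median 0.16; adjusted p = 0.366 with an estimated correlation), and Nr1d1, a repressor of Arntl, differed by 1.00 (SE 0.27, adjusted p 0.0887). In all, 17 lists passed at the preset correlation at this dose and 0 held with an estimated one. Among them were ciliated cells (median 0.27; adjusted p = 0.711 with an estimated correlation) and cell cycle (median -0.18; 0.708).

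Other rises at day 28 were those of Rgs2, a regulator of G protein signals (0.81, SE 0.148), Iigp1, an interferon-induced GTPase (0.73, SE 0.135), and DXBay18 (0.63, SE 0.098). Ch25h, which makes 25-hydroxycholesterol, rose by 0.79, Vnn1, a pantetheinase, by 0.72 and Rnase6, a secreted ribonuclease, by 0.72. Other falls were those of Ccnjl (-0.78, SE 0.124), Riox1 (-0.51, SE 0.0773), Hspa1b (-0.86), Rasl11a (-0.69) and Creb5 (-0.55); probes of Hspa1a and Hspa1b may not separate the pair. limma called 109 genes, 66 higher and 43 lower, with 3061 at an unadjusted p below 0.05 where chance expects 1194; 25 of the 109 differed by at least 1.5-fold. Neither the count nor the direction was stable: it called 2 genes with scaling between arrays (1 up, 1 down), 9 without the slide block (3 up, 6 down) and 97 with the software's ratios (45 up, 52 down).

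The count at day 28 moved widely with single animals. It was 58, 31, 754 and 32 without replicates 1, 2, 4 and 5 of 0 µg, and 60, 72, 72 and 40 without those of 486 µg, and without slides 2 and 10, a choice made after seeing the data, limma called 0 genes (1285 at an unadjusted p below 0.05). With 3 arrays of 162 µg that stood apart left out of the model, also chosen afterwards, it called 165. Of 20 named genes called here, 9 stayed called with each array left out: Dbp, DXBay18, Ahr, Pde4b, Klf4, Dnaja1, Ccnjl, Dnajb1 and Riox1. Rgs2 was lost without replicate 5 of 0 µg (adjusted p 0.0518), Iigp1 without its replicate 2 (0.0501), and Hlf without either or replicate 1 of 486 µg (up to 0.0883). Hspa1a was lost without replicates 1, 2 or 5 of 486 µg or 2 or 3 of 0 µg, and Hspa1b also without replicate 5 of 0 µg (each up to 0.101). Ch25h, Rnase6 and Fcrla were lost without replicates 1, 2 or 5 of either group or 4 of 486 µg (up to 0.139, 0.191 and 0.17). Vnn1 was also lost without replicate 3 of 0 µg (up to 0.101). Rasl11a and Creb5 were lost in 7 and 9 of the 10 leave-outs (up to 0.13 and 0.187).

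After the lower doses at day 28, Dnajb1 was 1.64-fold lower at 54 µg (-0.20 ± 0.173 against 0.51 ± 0.358; SE 0.118 on the log2 scale, n = 5, adjusted p 0.0411, 5 of 5 slides). It was the 1 gene called there, and 1437 had an unadjusted p below 0.05. That call ended when any array of 54 µg, or replicate 3, 4 or 5 of 0 µg, was left out (adjusted p up to 0.403). At 162 µg limma called 0 genes, with 1465 at an unadjusted p below 0.05. The smallest p there belonged to Pde4b (-0.81, SE 0.137, adjusted p 0.0538), Klf4 (-0.81, SE 0.152) and Klf7 (-0.39, SE 0.0739), the latter 2 with an adjusted p of 0.061. It called 4 without replicate 2 of 162 µg, 1 without replicate 2 of 0 µg, 5 without replicate 4 of 162 µg, 1 without slide 4 and 27 without slide 8. Saa3 differed by -0.15 at 54 µg and 0.74 at 162 µg, Timp1 by -0.10 and 0.05, Ccl2 by -0.29 and 0.14, Ccl7 by -0.15 and 0.30, Cxcl5 by 0.24 and 0.01, Spp1 by -0.40 and -0.20, Arg1 by 0.05 and 0.09 and Col1a1 by 0.10 and -0.04. Without replicate 3 of 162 µg, which stood 3.79 above the other 4 arrays, Saa3 differed by -0.17 (SE 0.6), and without replicate 5 of 54 µg Cxcl5 differed by -0.05 (SE 0.455). Clock genes at 162 µg had 0 called over all genes and 7 up and 3 down over the list alone (median 0.16; adjusted p = 0.227 with an estimated correlation). Monocyte and interstitial macrophage markers had medians of 0.15 and 0.19 at the lower doses, with an adjusted p = 0.525 and 0.524 with an estimated correlation. At each dose 11 lists passed at the preset correlation and 0 held with an estimated one.

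The early response to 486 µg differed from that at day 28. The difference (day 28 response minus day 1 response, log2) was -5.71 for Saa3 (SE 0.978, adjusted p 0.00686), -2.66 for Timp1 (SE 0.41, adjusted p 0.00205), -1.86 for Ccl2 (SE 0.363, adjusted p 0.0235) and -1.76 for Ccl7 (SE 0.266, adjusted p 0.00172), with 5 animals in each of the 4 groups. For Lcn2 it was -2.21 (SE 0.57, adjusted p 0.0918) and for Il1rn -0.46 (SE 0.12, adjusted p 0.0997), which did not pass. Of 26 acute phase genes, 6 had a lower response at day 28 (9 over the list alone; median -0.52, preset adjusted p 2.56e-13; adjusted p = 0.0536 with an estimated correlation). Of 18 neutrophil chemoattractants 0 were called over all genes and 8 were lower over the list alone (median -0.30). That list's call held, with an adjusted p = 0.00994 with an estimated correlation. CC chemokines had 2 lower (3 over the list alone; adjusted p = 0.22 with an estimated correlation), and heat shock genes 0 over all genes and 11 lower over the list alone (median -0.41; adjusted p = 0.148 with an estimated correlation). Of the genes that led at day 28, Ahr (0.78, SE 0.149, adjusted p 0.019), DXBay18 (0.68, SE 0.139, adjusted p 0.0338) and Riox1 (-0.54, SE 0.109, adjusted p 0.0338) passed. Dbp differed by 0.34 between the times (adjusted p 0.845), Pde4b by -0.75 (0.0919), Klf4 by -0.69 (0.194), Dnajb1 by -0.52 (0.215) and Hspa1a by -1.12 (0.164), none of which passed.

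limma called 62 genes for this difference at 486 µg, 39 with a higher and 23 with a lower response at day 28, and 2422 had an unadjusted p below 0.05; 31 differed by at least 1.5-fold. The majority turned to a lower response with the software's ratios (9 higher, 15 lower), Cy5 alone (14 and 25), scaling between arrays (0 and 6) and without the slide block (1 and 8). Leaving out any slide but 8 or 9 took the count to between 13 (slide 1) and 37 (slide 6), with 20, 19, 16, 26, 29 and 17 without slides 2, 3, 4, 5, 7 and 10. At 54 µg it called 1 gene, Pde4b (-1.17, SE 0.194, adjusted p 0.0436), with 1032 at an unadjusted p below 0.05. Of the 10 slides left out in turn, the call of Pde4b held only without slide 7; slide 5 left out gave 3 other genes and each of the other 8 gave 0. In 0 µg lungs Pde4b stood 0.78 higher at day 28 than at day 1 (adjusted p 0.62). At 162 µg it called 0 genes (1115 at an unadjusted p below 0.05). Of the lists, 14 at 54 µg and 12 at 162 µg passed at the preset correlation and 0 held with an estimated one, the lowest adjusted p with an estimated correlation being 0.0845 for heat shock at 54 µg.

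The trend over the 4 dose steps at day 1 gave the same leading genes. Saa3 rose by 1.92 per step (SE 0.219, adjusted p 6.17e-06), Timp1 by 0.86 (SE 0.0918), Ccl2 by 0.49 (SE 0.0811) and Il1rn by 0.24 (SE 0.0269), and limma called 101 rising and 32 falling genes. Most of the step came at the top: Saa3 was higher at 486 than at 162 µg by 4.56 (SE 0.692, adjusted p 0.000712), Timp1 by 2.15 (SE 0.29) and Ccl7 by 1.38 (SE 0.188), and 74 genes were higher and 9 lower in that comparison. The 133 trend genes became 70 and 37 and 87 without slides 1, 7 and 9, and the 83 step genes 25, 52 and 48 without slides 1, 3 and 7. At day 28 Dbp rose by 0.65 per step (SE 0.0981, adjusted p 0.00272), Pde4b changed by -0.27 (SE 0.0434), Klf4 by -0.27 and Hspa1a by -0.34 (SE 0.0743), and limma called 71 rising and 52 falling genes. Those 123 became 51, 33, 262 and 6 without slides 2, 4, 8 and 10. Between 486 and 162 µg at day 28 limma called 0 genes (1136 at an unadjusted p below 0.05).

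Lungs given 0 µg did not differ detectably between the times. limma called 0 genes with the slide as a random block, and 592 had an unadjusted p below 0.05. Saa3 differed by 0.01 (SE 0.82), Timp1 by 0.02 and Dbp by 0.12.

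The responses to 486 µg shared few called genes between the times. Both calls rose for 5 genes (Ccl12, Ch25h, Dbp, Tlr2 and Vnn1, where 0.39 would be shared if the calls were independent), both fell for 1 (Rasl11a), and Plaur, the urokinase receptor, was higher at day 1 and lower at day 28. Across all genes, which are not independent replicates, the 486 µg responses at day 1 and day 28 correlated at r = 0.0938, against -0.0333 to 0.0422 in simulations without any response. At 54 and 162 µg r was 0.16 and 0.0556, with simulated limits of 0.0521 and 0.0398. All simulations given here drew noise independently for each gene, while real arrays can deviate in many genes together. Their limits can therefore be too narrow, and they do not decide whether a response was shared between times or doses. Between doses of 1 time, which share their 0 µg arrays, simulations without a response gave a mean r near 0.50 (0.499 to 0.502). At day 1 the observed r was 0.276 (54 with 162 µg), 0.352 (54 with 486 µg) and 0.489 (162 with 486 µg), and the covariance differed from the simulated one by -0.00414, -0.00183 and 0.00147. At day 28 r was 0.627, 0.672 and 0.705 and the covariance exceeded the simulated one by 0.00331, 0.0076 and 0.00762. With the 0 µg arrays split between the doses, mean r was -0.0738, 0.02 and 0.137 at day 1 and 0.0156, 0.161 and 0.141 at day 28, and single splits at day 28 ranged from -0.542 to 0.616. Each dose then rested on only part of its own animals too, so these values do not compare directly with r from all animals.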

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

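The tests of the genes called at day 28, of the clock genes and of the arrays of 162 µg that stand apart were chosen only after the results were seen, while the interaction tests, the search for single arrays and the regroupings were set beforehand, apart from those of trends and differences between times within slides. The bound for the share of the slides was made stricter after the value 0.772 had been seen just past the first bound, and it is left open for that reason. The mixing of reference RNA was first tested by the spread of 451 lung genes, 2.06 and 1.18 on the 2 arrays against 0.445 to 1.37 on the others, and the step used below replaced it after those values were seen.

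The response to 486 µg differed between the times by limma's interaction test for 14 named genes. The day 28 response was lower, in log2 units, by -5.71 for Saa3 (SE 0.978), -3.21 for Saa1 (SE 0.428), -2.66 for Timp1 (SE 0.41), -2.07 for Saa2 (SE 0.248), -1.87 for Orm2 (SE 0.274), -1.86 for Ccl2 (SE 0.363) and -1.76 for Ccl7 (SE 0.266). It was also lower by -1.38 for Noxo1, an organiser of an NADPH oxidase (SE 0.306), -0.83 for Il1r2 (SE 0.148) and -0.54 for Riox1 (SE 0.109). It was higher by 0.68 for DXBay18 (SE 0.139), 0.69 for Ogn (SE 0.154), 0.78 for Ahr (SE 0.149) and 0.85 for Gstm1 (SE 0.185). Adjusted p ran from 0.000101 for Saa2 to 0.0476 for Noxo1 and Ogn.

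Single arrays lay far from the other 4 of their group in 9 of 211 sets of a gene and a group, where about 1 in 20, or 10.6, arise by chance. In replicate 3 of 54 µg at day 1, Saa3 was 5.28 and Timp1 2.78 above the mean of the other 4 (log2). In replicate 3 of 162 µg at day 1, Spp1 was 2.42 and Ccl2 2.05 above it. In replicate 3 of 162 µg at day 28, Saa3 was 3.79 above it. Asgr1 in replicate 4 and Arntl in replicate 5 of 486 µg at day 1 differed by -1.20 and -1.03. C1ra in replicate 2 of 0 µg at day 1 and Cxcl5 in replicate 5 of 54 µg at day 28 were 0.46 and 0.66 above it.

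The first pattern weighed is the set of 109 genes called at day 28 after 486 µg, whose number swings with single animals. That a few slides carry the calls stays open: the median change in the called direction was 0.419, 0.548, 0.309, 0.303 and 0.595 on slides 2, 4, 6, 8 and 10, with a ratio of 0.772 for slides 4, 6 and 8 over slides 2 and 10 that does not describe the single slides, and between 106 and 109 of the genes had the called sign on each slide. A change that grows with dose stays open too, since the step from the lower doses to 486 µg made up 0.433 of the whole difference, where chance alone gives 0.5. The same genes moved in that direction at 54 µg (median 0.224) and 162 µg (0.261), for 108 and 109 of the 109, but all 3 doses are set against the same 5 animals of 0 µg, so that a few unusual 0 µg animals could also produce this. Without replicate 4 of 0 µg 754 genes were called and without replicate 2 31, so a difference among the 0 µg animals and an effect of the particles cannot be told apart for this set.

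The second pattern is the shift of clock genes at 486 µg. Genes that rise with Dbp, averaged, lay above those that rise with Arntl on 10 of 10 slides, by 0.91 at day 1 (SE 0.181) and 0.891 at day 28 (SE 0.127). That count is not independent support, since Dbp at both days and Arntl at day 1 had been named for 1 sign on all 5 slides. At day 28 the difference lay above 0 on 5 of 5 slides at 54 and at 162 µg too, against the same 0 µg animals. Lungs collected at different times of day could give this shift, although any shift of the clock would give the same. A clock response that grows with dose stays open. The difference was 0.343, 0.817 and 0.891 over the 3 doses at day 28, and 0.332, 0.268 and 0.91 at day 1. The lowest step of -0.064 is smaller in size than 0.226, the largest SE of these differences from 0 µg. No SE of the step itself was computed. The tables argue against neither, the labels give no time of day, and a collection in order of dose would join dose and time.

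The third pattern is a set of 3 arrays of 162 µg that stand apart, all values being log2 above the other arrays of the slide. For replicate 5 of day 1, an effect of 162 µg on the granulocyte genes Mpo and Camp is argued against, since they were 4.81 and 4.62 there and at most 0.059 in the other 4 arrays. Bone marrow cells in that sample may account for it, as Slc4a1 of red cells was 2.61 and the medians of the cell cycle and erythroid lists were 0.534 and 0.426, while S100a9 of mature neutrophils was 0.882. The cell cycle median does not single out such cells. It was 0.665 in replicate 3 of day 1 and 0.646 in replicate 4 of day 28, where Mpo was -0.253 and 0.0929. For replicate 3 of day 1, a small share of reference RNA mixed into the sample is argued against as the whole cause. It would lower weakly and strongly lung-enriched genes nearly alike. The medians were -0.547 for 160 genes 8 to 11-fold higher in lung and -3.59 for 20 genes at least 64-fold higher. That is a step of -3.04 (SE 0.436), against -0.574 to 1.22 on the other 38 arrays. A large share would lower strongly enriched genes more, so the step does not test it. Genes far below the reference, picked by hand, were higher there, as mixing would also give: Dlk1 3.08, Birc5 1.99, Hmga2 1.87 and Mki67 1.72. For replicate 4 of day 28 mixing of reference RNA stays open. Its step of 0.416 (SE 0.107) lies among those of the other 38 arrays, and the median of 451 genes at least 8-fold higher was -0.65. Sftpc (0.539), Hba-a1 (0.685) and Hbb-bt (0.589) were higher, and Scgb1a1 (0.0442) and Cldn5 (-0.000295) near 0. The log2 ratios of this array had a slope of 0.684 on the median array, the lowest of any array. They correlated with the deposited values at r = 0.939, also the lowest, and loess ratios without background subtraction did so at 0.995. An effect of background correction on the scale of this array was not separated from mixing. A different piece of lung was not tested for either array.

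Regrouping the arrays asked how often other groupings of the same arrays, 100 per comparison with the real one included, called as many genes. At day 1, 486 against 0 µg called 187 in 1 of 100, the real one, and at most 32 otherwise. For 486 against 162 µg it was also 1 of 100 (91 with missing values filled in, at most 15 otherwise). These groupings cross slides and lose the balance of 1 animal of every dose per slide, which can itself lower their counts. They therefore do not exclude chance on their own. As many genes were called in 2 of 100 for the trend at day 1 (133, highest other 196) and at day 28 (123, highest other 979). It was also 2 of 100 for the difference between times at 486 µg (63 with missing values filled in, highest other 460). For that at 54 µg (1, highest other 1) it was 2 of 100 as well, and all of these groupings cross slides too. With doses exchanged within slides only, again 100 each, as many genes were called in 1 for the trend at day 1 (highest other 1), which argues against chance for that trend. For the difference at 486 µg it was 2 (highest other 72), and for that at 54 µg, a single gene, also 2 (highest other 1). Regrouping doses, within or across slides, also breaks an effect of dose at 1 time alone. It therefore does not decide whether the responses differed between the times. For the trend at day 28, 5 of the 100 within slides called as many (highest other 1245), so chance could not be excluded there. For 54 µg at day 28 (1 gene), 4 of 100 groupings across slides called as many (highest other 200), and of the 16 that swap animals within slides 2 did. For 486 against 0 µg at day 28 chance could not be excluded: 8 of 100 groupings called 109 or more, and 1 called 2365. Groupings that call many times the real number point to a structure of the samples, which was not identified. Of the 16 groupings within slides, too few for a share that excludes chance, the real one alone called any gene in this comparison and for 486 against 0 µg at day 1, and for 486 against 162 µg at day 1 the highest other called 2. For comparisons with 0 calls all 100 groupings match by construction, so their share says nothing about chance. Their highest others were 1 (54 µg, day 1), 1 (162 µg, day 1), 2698 (162 µg, day 28), 310 (difference between times at 162 µg), 110 (486 against 162 µg, day 28) and 4 (between times at 0 µg).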

How the results depend on the processing

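Leaving out slides, leaving out slides 2 and 10 together and leaving out 3 arrays of 162 µg were chosen only after the results were seen; the other settings were set beforehand. No called value of a named gene changed sign, and of the called lists 1 median did, that of alveolar type 2 cell markers at 486 µg of day 28 (0.24, and -0.00592 with the software's ratios, where its call was lost). Values that were not called could change sign, as for Timp1 at 54 µg on day 1 (0.44, and -0.02 without replicate 3). Under other settings 3022 values of named genes stayed on their side of the threshold, 417 lost their call and 34 gained one. At 486 µg, 10 of 40 called named genes of day 1 (Saa3, Lcn2, Saa1, Saa2, Orm2, Noxo1, Il1rn, Ccl12, Ccl17 and Il1r2) and 0 of 20 of day 28 kept their call under all 22 settings set beforehand. Of the list calls, 4 held and 122 were lost with an estimated correlation, and among the same calls 37 were lost with the software's ratios, 5 without the slide block and 3 without a filter on dim probes. Comparisons with 0 calls are open below the signal that stands over background. Using the 20 arrays of 1 time was not run for the comparisons between times, which need both. Replicate numbers carry nothing beyond the slide, which is already a block. Unless a reason is given, the cause was not tested.

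Genes called, in the order day 1 at 486 µg (187), day 28 at 54 µg (1), 162 µg (0) and 486 µg (109), the difference between times at 54 µg (1) and 486 µg (62), trend at day 1 (133) and day 28 (123), and 486 against 162 µg at day 1 (83), are given only where they moved by more than 1.5 times. Without the slide block, which leaves slide differences in the error, they were 47, then 0 at 54 µg and 9 at 486 µg of day 28, 0 and 9 for the differences, 36 and 7 for the trends and 23 for 486 against 162 µg. With the slide as a random block day 28 had 2 at 54 µg and 9 at 162 µg, and the difference at 54 µg had 5. Without background subtraction day 28 had 3, 8 and 176 (88 up and 88 down, against 60.6% up), the difference at 54 µg 0, the trend at day 28 185 and 486 against 162 µg 159 (73.6% up against 89.2%). The software's ratios gave 0 at 54 µg of day 28, 0 and 24 for the differences (37.5% up against 62.9%), and 46.4% up at 486 µg of day 28. The deposited table gave 3 and 4 at 54 and 162 µg of day 28, 0 for the difference at 54 µg, 51.5% up for that at 486 µg and 172 for 486 against 162 µg (74.4% up). Cy5 alone gave 0 and 39 for the differences (35.9% up for the latter), 78 for the trend at day 28 and 72.5% up for 486 against 162 µg. Scaling between arrays gave 46 (89.1% up against 75.4%), then 0 at 54 µg and 2 at 486 µg (1 up, 1 down) of day 28, 0 and 6 for the differences (0 up), 37 and 6 for the trends (97.3% up against 75.9% at day 1) and 35.

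The stricter filter on dim probes gave 1 at 162 µg of day 28, and no filter moved none. The mean over probes gave 0 at 54 µg of day 28 and 0 and 36 for the differences. With 20 arrays, which have fewer residual degrees of freedom, day 1 had 95 at 486 µg, 74 for the trend and 40 for 486 against 162 µg, and day 28 had 0, 2 and 38 for the doses and 33 for the trend. Array weights, of which replicate 4 of 54 µg at day 28 took 83.7 and no other array over 2.68, so that 1 array dominates the fit, gave 1 at 54 µg (0 otherwise) and 324 at 486 µg of day 1, 122 at 54 µg and 672 at 486 µg of day 28, 28 and 291 for the differences, 285 and 207 for the trends and 181. A 1.5-fold minimum, which can only remove genes, gave 74, 25, 31 for the difference at 486 µg and 34 for 486 against 162 µg. For the trends it gave 5 and 1, but there it asks for 1.5-fold per dose step, a stricter bound than for the other comparisons. Without slides 2 and 10, fewer animals, day 28 had 0 at 54 µg, 0 at 486 µg and 0 for the trend, and the differences 0 and 2. Without the 3 arrays of 162 µg day 28 had 6 at 162 µg, 165 at 486 µg and 220 for the trend, the difference at 486 µg was 115 and 486 against 162 µg 44.

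With 1 array or 1 slide left out in turn, the counts ranged from 65 (slide 7) to 163 at 486 µg of day 1, from 0 to 6 (slide 8), 0 to 27 (slide 8) and 15 (slide 10) to 754 (replicate 4 of 0 µg) at the 3 doses of day 28, from 0 to 3 and 13 to 88 for the differences at 54 and 486 µg, from 37 to 120 and 6 to 262 for the trends and from 25 to 64 for 486 against 162 µg. With the 0 µg arrays split, the correlations between doses fell from 0.276, 0.352 and 0.489 to -0.0738, 0.02 and 0.137 at day 1. At day 28 they fell from 0.627, 0.672 and 0.705 to 0.0156, 0.161 and 0.141. The doses then shared no arrays, but each was also estimated from only part of its slides. Fewer treated animals entered as well, so the fall need not come from the shared arrays alone.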

Other observations

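The genes and tissue markers given here were chosen after their values were seen, and no explanation was tested for them. At day 1 after 486 µg limma also called single genes that were picked here by hand and not tested as a group. Pdia6, a disulphide isomerase of the endoplasmic reticulum, rose by a log2 of 0.50, Dnajb11, a co-chaperone there, by 0.42, Rpn1, part of the enzyme that attaches sugar chains, by 0.37 and Ssr1, of the translocon, by 0.37. Uhrf1, which helps to maintain DNA methylation, rose by 0.92, Mcm7 by 0.50 and Mcm4 by 0.37, while the cell cycle list had a median of 0.03 (adjusted p = 0.805 with an estimated correlation). Other rises, some in genes of the lists, were Ch25h (1.37), Acod1, which makes itaconate in activated macrophages (1.27), Cxcl1, a neutrophil chemoattractant (1.27), Cp, the copper carrier ceruloplasmin (1.20), Ccl9 (1.16), Il1b (0.89), Csf2 (0.84), Cd14 (0.80) and Sod2 (0.39). Among the falls were Aox1, aldehyde oxidase (-0.53), and Ces1g, a carboxylesterase (-0.53).

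At day 28 after 486 µg Tlr2 (0.55), H2-Oa, a class II histocompatibility gene (0.55), and Id2 (0.48) were also higher. Srf, a regulator of immediate early genes (-0.43), Chordc1, a heat shock protein partner (-0.46), and Mcl1, a survival factor (-0.41), were lower.

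Single arrays differed from the other arrays of their slide in genes of tissues that lie beside lung or of lung cells. Values are log2 above the other arrays of the slide unless stated otherwise. Replicate 1 of 162 µg at day 28 had Nppa of heart atrium at 3.43 and Adipoq of fat at 4.43. Clca1 of goblet cells was 5.95 there, with medians of 2.09 for the cardiomyocyte list and 2.71 for the adipocyte list. As a deviation from the mean over all arrays, its cardiomyocyte list lay at 1.49. Its slide mates of 54, 0 and 486 µg lay at -1.11, 0.0372 and -1.04. Replicate 5 of 54 and 486 µg at day 28 lay at 1.5 and 1.51. High cardiomyocyte values were therefore not confined to replicate 1 of 162 µg. The adipocyte list lay at 2.35 in replicate 1 of 162 µg, against 1.3 and 1.37 in replicate 5 of 54 and 486 µg. Replicate 5 of 0 µg at day 28 had Alb and Serpina1d of liver at 3.22 and 2.43, and replicate 4 of 162 µg at day 28 had Alb at 1.6. Replicate 3 of 162 µg at day 1 had Sftpc of alveolar type 2 cells at -4.13, Scgb1a1 of club cells at -4.05, Cldn5 of endothelium at -3.37 and Hbb-bt of red cells at -5.37, with Dlk1 at 3.08.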
